A study of Mus musculus with 1049 samples.

How the data were processed

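Single dermal fibroblasts of newborn, young and old C57Bl/6 mice were profiled with Smart-seq2, 1 cell per plate well. The values used were raw read counts per gene and cell, deposited by the authors as 1 table per plate. The submitters' processing notes name the genome build GRCm38 and FastQC; the aligner, the counting program, the strand setting and the treatment of reads shared between genes are not given in the sources used here. Values of gene families with near-identical members (H2-D1, Serpina3c and Serpina3g, Mt1, Ly6a, the globin genes) and of overlapping or antisense genes depend on those settings and are uncertain to that extent. All values in the tables were whole numbers, as raw counts require.

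The labels held 1049 columns on 11 plates with age and experiment for each; 5 columns without any value were left out and 1044 were used. Well by well, 2 pairs of plates of experiment 1 had median correlations of 0.994 and 0.994, against at most 0.363 for every other pair of plates, so each pair was taken as 1 plate sequenced in 2 runs and the runs of a well were added (183 wells). Median chi-square per degree of freedom between runs was 2.79 and 8.14. That left 861 wells on 9 plates. The plates came with 2 gene annotations of 51826 and 52636 entries; the 51777 entries common to both were kept and 908 left out. Of the common genes 51633 were matched by identifier to GENCODE M21, which gave symbols and positions, and these held 99.9% of the reads; 144 were not matched. Spike-in entries were left out of all sums.

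Cells were kept with at least 50000 reads on genes, at least 1000 genes with a read and at most 25% mitochondrial reads. This kept 249 of 256 newborn (97.3%), 246 of 287 young (85.7%) and 240 of 318 old wells (75.5%). Of the 126 wells left out, 124 had too few genes, 106 too high a mitochondrial share and 27 too few reads, with overlap. Kept cells held 246349 to 4331293 reads. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 20 principal components, 15 neighbours, resolution 0.5, seed 20); 4 of 5 clusters, with 725 cells, were fibroblast-like by marker lists, and 10 cells in the other cluster were given no name and stayed in the main comparisons. Clusters 1 and 2, led by Il1r2 with Ly6a and Il1r2 with Aldh3a1, held 0 newborn cells. Cluster 4, led by Nrep and Gpc3, held 140 and 84 newborn cells of experiments 1 and 2 and at most 4 cells of any adult sum. Cluster 5, led by Pclaf and Stmn1, held 18 and 7 newborn cells and 0 adult cells, and the unnamed cluster was led by Spp1 and Apod. Cells were sorted singly, and no doublet caller was run.

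Cells are not independent replicates, and the labels name experiments and no mice. Reads were therefore added over the kept cells of each age and experiment, giving 6 sums and n = 2 per age. The sums held 171717204 and 119682449 reads (newborn, experiments 1 and 2), 168514132 and 151799592 (young) and 155497099 and 195324769 (old). A count of 0 over both sums of an age was given a floor of 3 reads, equal to 0.00859 CPM in newborn, 0.0105 in young and 0.00916 in old sums. Bounds on fold changes below rest on this floor, which covers the counting of reads and not the draw of cells. In a principal component analysis of the sums the first component held 38.3% of the variance and parted newborn from adult sums (-240 and -252 against 101 to 147). The second held 17.3% and parted the 2 old sums from each other (245 in experiment 1 and -71.5 in experiment 2, against -79.8 and -106 in young sums), and the third parted them too (-18.2 and 223.8).

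Ages were compared with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, age as the only term, 16684 genes tested, Benjamini-Hochberg threshold 0.05). The common biological coefficient of variation was 1.13, with 3 residual degrees of freedom. The experiment is a batch shared by the ages and given by the labels, and a fit with it as a block was an alternative. Across genes, deviations of the sums of an experiment from the mean of their age correlated at 0.0125 (old and young), -1.7e-04 (young and newborn) and 0.0107 (old and newborn). The fit without a block was kept as planned. Such correlations do not exclude a shared experiment effect on part of the genes. With cells thinned to equal reads, the median number of genes with a read was higher in experiment 2 at every age. Experiments 1 and 2 had 1799 and 2226 in newborn, 1648 and 2043 in young and 1503.5 and 1700.5 in old cells. Gene lists of at least 3 measured members were tested with camera of limma 3.58.1 (correlation preset to 0.01), adjusted over the lists of a comparison, and members were also adjusted over the list alone. Lists, tests and the rule for naming genes were set before the data were examined.

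The rule named, per comparison, up to 10 genes with the most positive and 10 with the most negative log2 fold change among those past the threshold, with the same direction in both experiments and at least 10 CPM in the higher age, leaving out predicted and clone names. From each list it took up to 4 members past the threshold by smallest p and up to 2 others by highest mean CPM. Where fewer than 10 genes passed, it took the 5 with the smallest p per direction as well. Genes encoding sort markers and sex-linked genes were always included. A comparison's text gives part of the genes the rule names.

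Measures over single cells used cells thinned without replacement to 100000 reads (no kept cell was lost), with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Distance between cells was 1 minus the Spearman correlation of log2(CPM + 1) over 8229 genes with a mean of at least 10 CPM, averaged over all pairs of an age and experiment. Variability was the median log2 ratio of squared coefficients of variation over genes with means within 1.5 times of each other. Marker scores were mean z-scores of 18 papillary and 19 reticular genes, and the proliferation share was the percent of cells with a read in at least 5 proliferation genes. Values of 2 against 2 sums were compared with exact two-sided permutation tests, which cannot go below 0.333. Figures were drawn with matplotlib 3.10.9.

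The procedure was tested on simulated data, sums with 200 genes changed by known factors. Counts were drawn independently for each gene, with the dispersions that edgeR estimated from these data. In old against young, run on 16069 genes, edgeR recovered 0, 1.49 and 37.9% of genes changed 2-fold, 4-fold and 16-fold, with 0 false calls. In young against newborn (16109 genes) it recovered 0, 1.52 and 42.4% with 4 false calls, and in old against newborn (16113 genes) 0, 0 and 37.9% with 1. DESeq2 1.42.0 recovered 11.9, 40.3 and 84.8%, then 10.4, 40.9 and 81.8%, then 4.48, 34.3 and 87.9%, with 437, 507 and 452 false calls. Camera found the moved list (adjusted p 1.0e-08, 2.2e-06 and 9.3e-06) and 0 others. The simulated genes were uncorrelated, so false calls of correlated lists were not tested. In the data, ribosomal protein genes, for example, had an estimated correlation of 0.469 between old and young. A simulated log2 ratio of variability of 1 between old and young was estimated at 0.859 and 0.874, and no change at -0.00657 and 0.0121.

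Alternatives set in advance were DESeq2, its size factors in edgeR, other filters on genes and cells (the stricter cell filter asked for 200000 reads, 2000 genes and at most 15% mitochondrial reads), thinned cells, fibroblast-like clusters only, the experiment as a block, only 2 ages in the fit, leaving out each sum, camera with an estimated correlation, fry, and for the cell measures other depths (50000 and 250000 reads), genes, distances and thresholds. Chosen after seeing the data were a filter on genes read in at least 10% of the cells of 1 age, limma (on those genes) and camera on mean log2(CPM + 1) per cell, the first run only of wells run in 2 runs, and the fit without 1 young cell.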

Results

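Dermal fibroblasts of C57Bl/6 mice were compared at 3 ages. Newborn mice were 1.5 or 2.5 days old, young mice 2 months and old mice 18 months. Fibroblasts, sorted after staining for markers of immune, mast, epithelial and endothelial cells and for CD34 and Pdgfra, were placed singly in plate wells and sequenced with Smart-seq2. The method copies polyadenylated RNA along its full length and adds no molecular identifiers. The 861 wells lay on 9 plates, 5 in experiment 1 and 4 in experiment 2, and each plate held all 3 ages. Of these, 735 cells were kept, 249 newborn, 246 young and 240 old. Median depth was 1068178 reads on genes per newborn cell, 1187652 per young cell and 1381116 per old cell. The median number of genes with a read was 2390, 2130 and 1981.5. Reads of the kept cells were added up per age and experiment, which gave 6 sums of 119682449 to 195324769 reads and n = 2 sums per age. Levels below are counts scaled to library size times the TMM factor (CPM), as mean ± SD of the 2 sums of an age. Log2 fold changes carry a standard error computed as their absolute value over the square root of edgeR's F statistic. The labels name experiments and no mice, so p-values of single genes measure only the spread between these 2 experiments. Camera's p-values with a preset correlation compare the genes of a list with all other genes, taken as nearly independent. They do not measure the spread between experiments. With an estimated correlation, camera also drops to the 3 residual degrees of freedom of the fit, so few lists could pass. A call lost there does not by itself mean that the genes of a list were correlated. The 2 old sums lay far apart on the second principal component of the sums (245 and -71.5, 17.3% of the variance), while the 2 sums of newborn and of young dermis lay closer (7.54 and 4.95; -79.8 and -106).

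The kept cells carried fibroblast genes and few reads of Ptprc, Kit, Epcam and Pecam1, the genes of 4 lineage markers named in the sorting. Col1a1 and Col1a2, the chains of type I collagen, and Dcn, the proteoglycan decorin, were read in at least 95.2% of the cells of every sum after thinning each cell to 100000 reads (96.8% without thinning). Ptprc, which encodes the immune marker CD45, had 0 reads in all 735 cells, which allows a share of up to 0.408% of cells with a read (3 cells, counting error only). Kit had 2 reads in 1 cell, Epcam 68 reads in 2 newborn cells, and Pecam1, an endothelial gene, 2346 reads in 1 newborn cell and 214 in 2 young cells. Other markers of those lineages were present at low mean levels but in more cells. The keratin gene Krt10 was at 19.1 ± 4.66, 45.5 ± 2.65 and 58.5 ± 1.96 CPM in newborn, young and old sums, and the endothelial gene Plvap at 8.88 ± 4.57, 58.2 ± 26.2 and 58.4 ± 12.7 CPM. After thinning, Krt10 was read in 22.8 and 15.4% of newborn, 28.2 and 43.3% of young and 34.1 and 30.7% of old cells. For Plvap the shares were 8.86 and 7.69%, 28.2 and 29.8%, and 27.8 and 15.8%. Csf1r, a macrophage receptor gene, was read in 16.2 and 14.4% of young cells after thinning (17.6 and 14.4% without). Cd24a, whose protein the labels say was not used for lineage selection, was read in 19.6 and 31.9% of newborn cells (22.8 and 31.9% without thinning) and in 0 adult cells. Cd34, encoding a sorting marker, was read in 60.8 and 72.5% of newborn cells in experiments 1 and 2, 96.5 and 98.1% of young and 93.7 and 99.1% of old cells after thinning (62.7 and 76.9%, 97.2 and 98.1% and 95.2 and 100% without thinning). Pdgfra, also among the stained markers, was read in fewer cells. Its shares were 30.4 and 48.4% of newborn, 21.8 and 42.3% of young and 18.3 and 29.8% of old cells after thinning. Without thinning they were 32.9 and 50.5%, 23.2 and 46.2%, and 19.8 and 33.3%. Xist, expressed from the inactive X chromosome of females, was read in 61.9 to 92.3% of the cells of each sum after thinning (65.9 to 92.3% without), and 4 Y-linked genes had at most 4 reads in any sum.

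Between young and old dermis, type I and type III collagen messages and Sparc, which encodes a collagen-binding matrix protein, were several-fold lower at 18 months than at 2 months. Col3a1 was at 19161 ± 967 CPM in young and 3441 ± 242 CPM in old sums (5.57-fold lower, log2 fold change -2.48 ± 0.16, n = 2 sums per age), and Sparc at 13607 ± 496 and 2297 ± 108 CPM (5.92-fold lower, -2.57 ± 0.17). Col1a2 was at 20964 ± 3556 and 4764 ± 950.3 CPM (4.40-fold lower, -2.14 ± 0.24), while Dcn (108226 ± 5730.2 and 111716 ± 6383 CPM) and Lum, encoding the proteoglycan lumican (18356 ± 102 and 17618 ± 808 CPM), differed by less than 1 SD of the old sums. Col3a1 lies on chromosome 1, 45311538 to 45349706, Sparc on chromosome 11, 55394500 to 55423183 and Col1a2 on chromosome 6, 4504814 to 4541544 (GRCm38, GENCODE M21, 1-based). No gene of the 16684 tested passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By edgeR 810 had an unadjusted p under 0.05, which is below the share of 0.05 given on average without any difference. DESeq2 called 1047 of the 16684 genes. On the 6970 genes read in at least 10% of the cells of 1 age, edgeR called 9, and limma on mean log values per cell called 8. With the experiment as a block edgeR called 0 as well, with 640 at an unadjusted p under 0.05. Col3a1 and Sparc had the smallest p, both at an adjusted p of 0.128, and Col1a2 was at 0.727.

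The collagen list fell as a group. Its 19 measured members had a median log2 fold change of -1.28 between old and young (-1.58 in experiment 1 and -1.48 in experiment 2), 16 were lower in both experiments, and camera, a test of a list against all other genes, gave an adjusted p of 2.1e-14 over 33 lists. That call was lost at an adjusted p = 0.102 with an estimated correlation. The correlation estimated for this list was -0.0506, below the preset 0.01, so the loss was not due to a higher correlation. Fry, another test of lists, kept the collagen list at an adjusted p of 7.3e-04. Of the 4 lists called lower in old sums, fry kept only this 1. Adjusted over the list alone, 9 collagens were lower and 1 higher, against 0 over all genes. Genes for collagen processing and crosslinking fell too, with a median of -0.92 over 25 members, 18 of them lower in both experiments, and an adjusted p of 1.4e-08; this call was lost at an adjusted p = 0.597 with an estimated correlation, and 3 members were lower adjusted over the list alone. In that list Pcolce, an enhancer of procollagen cleavage, was at 1325 ± 113 CPM in young and 1038 ± 65.6 CPM in old sums. Alongside these lists, old cells had fewer genes with a read than young cells (medians of 1503.5 and 1700.5 against 1648 and 2043 in experiments 1 and 2 at 100000 reads), and Csf1r, a macrophage receptor gene, was at 98.5 ± 87.4 CPM in young and 11.6 ± 1.50 CPM in old sums.

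**Figure D1:**
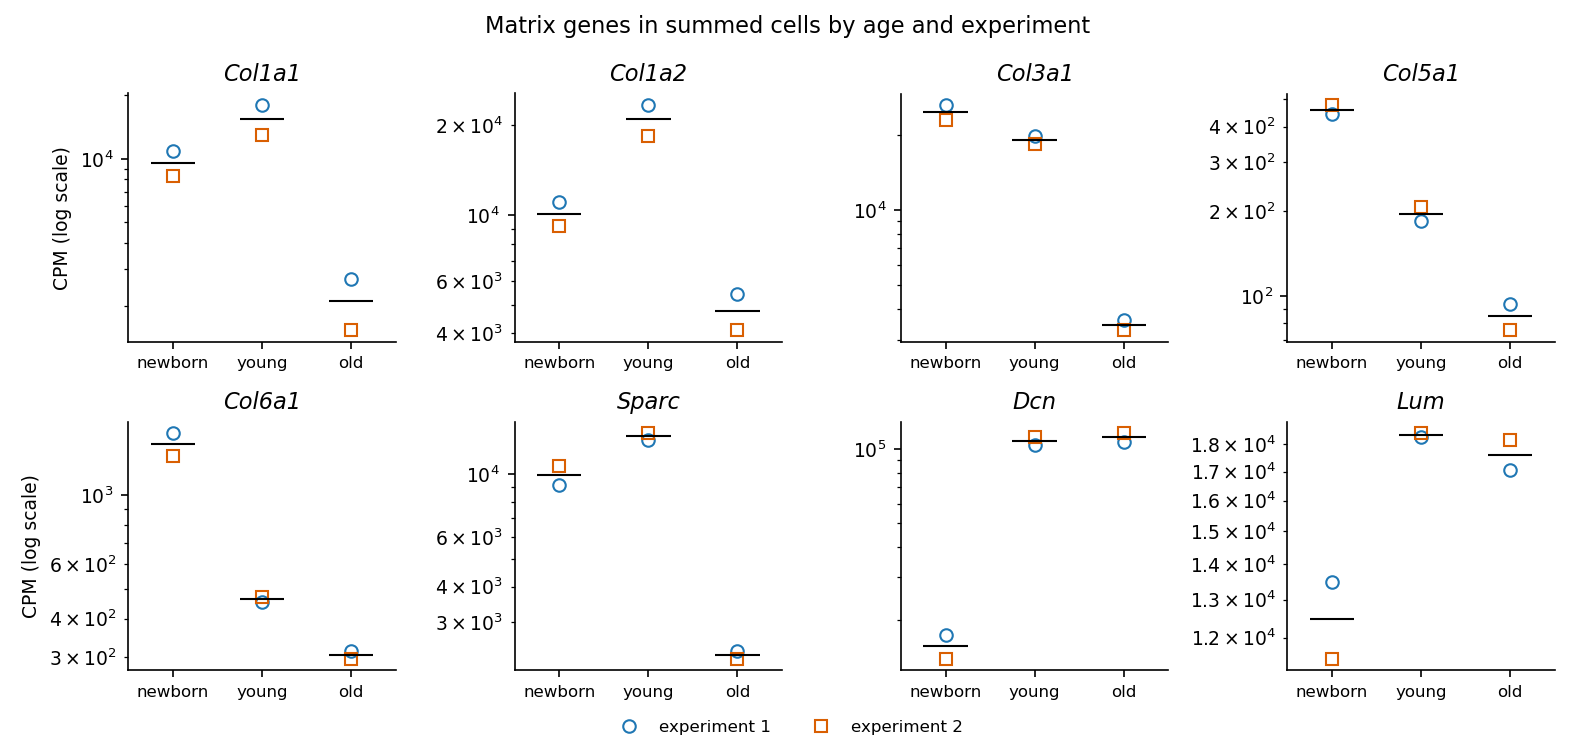
Levels of 8 matrix genes in CPM on a log scale, by age, with 1 point per experiment and a line at the mean of both. Col3a1 lies near 19161 CPM in young and 3441 CPM in old sums, Sparc near 13607 and 2297 CPM, while Dcn and Lum lie at similar levels in young and old sums.

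Among genes higher in old than in young sums, Enpp2 and Apoe had the smallest p and did not pass. Enpp2, encoding autotaxin, which makes the lipid mediator lysophosphatidic acid, was at 112 ± 0.980 CPM in young and 402 ± 63.2 CPM in old sums (3.58-fold higher, 1.84 ± 0.22). Apoe, a lipid-carrying apolipoprotein gene, was at 2510.5 ± 141 and 8332 ± 46.6 CPM (3.32-fold higher, 1.73 ± 0.21). Both had an adjusted p of 0.727 by edgeR. B2m and H2-D1, the light and a heavy chain of major histocompatibility complex class I, were at 5642 ± 1039 and 2654 ± 376 CPM in young and 9923 ± 762 and 3930.5 ± 35.0 CPM in old sums, and the chemokine gene Ccl11 at 2134.3 ± 27.2 and 3555 ± 930.1 CPM, none past the threshold (adjusted p 0.906, 0.910 and 0.910). Gpx3, encoding a secreted glutathione peroxidase, was at 5974 ± 3936 CPM in young and 1530.3 ± 232 CPM in old sums (-1.96 ± 0.54, adjusted p 0.906).

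Of the other lists, imprinted growth genes fell between young and old with an adjusted p of 7.3e-05 and a median of -4.32, or -3.74 with genes at 0 reads set to their bound (adjusted p = 0.767 with an estimated correlation). The median was 0 in experiment 1 and -3.28 in experiment 2, 7 of 19 members were lower in both, and without young replicate 2 the adjusted p was 0.136. Markers of reticular fibroblasts, the deep dermal lineage, fell with an adjusted p of 0.0165 and a median of -0.33 (adjusted p = 0.767 with an estimated correlation), a call lost without newborn replicate 1 or 2, young replicate 2 or old replicate 2 (adjusted p 0.120, 0.125, 0.136 and 0.447). Its member Ly6a, encoding the sort marker Sca1, was at 4459.7 ± 1339.8 and 4531 ± 1123 CPM. Ly6a changed sign when cells were thinned (-0.01) and with limma on mean log2(CPM + 1) per cell (-0.10), where tool and genes tested differ too. The remaining 29 lists did not pass (adjusted p 0.164 to 0.992). Among them were the senescence and secretory list (median 0.03, adjusted p 0.992), interferon response and antigen presentation (0.01, 0.385), adipogenic and lipid storage genes (0, 0.902) and papillary markers, of the upper dermal lineage (0, 0.902).

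The count of 0 genes between old and young depended on the tool and the genes tested. DESeq2 called 398 genes higher and 649 lower, of which 584 had at most 3 reads in 1 of the ages. On simulated sums without a change in most genes it made 437 false calls among 15850 unchanged genes, and edgeR 0. The simulation used dispersions estimated by edgeR, so it does not compare the tools on equal terms. Without a filter on low counts, Sparc and Col3a1 passed, both lower. Among the 6970 genes read in at least 10% of the cells of 1 age, a filter chosen after the data were seen, edgeR called 9 genes lower and 0 higher. These were Col3a1, Sparc, Col1a2 and 6 genes read in few young cells, Sytl2, Bdnf, Sfrp2, Pak3, Hmgb3 and Slc25a26; Bdnf, for example, was read in 2.11 and 0.962% of young cells thinned or not and in 0 old cells. On mean log2(CPM + 1) per cell over the same 6970 genes, also chosen after the data were seen, limma called 2 genes higher and 6 lower. The lower ones were Col3a1, Sparc, Col1a2, Col1a1, Col5a2 and Cgref1, and the higher ones Ldhb and Rxfp1, a relaxin receptor gene read in 17.5 and 19.3% of old cells and 0 and 0.962% of young cells after thinning (18.3 and 21.1% against 0 and 0.962% without). Sytl2, Pak3, Slc25a26, Col1a1, Col5a2, Cgref1 and Ldhb are named here after their values were seen.

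Between newborn and young dermis, H2-D1, Serping1, Ccl11 and Apoe were among the genes that rose. H2-D1 rose from 92.8 ± 16.1 to 2654 ± 376 CPM (28.6-fold, 4.84 ± 0.24), and Psmb8 and Psmb10, subunits of the immunoproteasome that trims antigen peptides, rose 74.9-fold and 27.4-fold. Serping1, the C1 inhibitor of the complement cascade, rose from 215 ± 58.9 to 8768 ± 339 CPM (40.8-fold, 5.35 ± 0.27). Ccl11, the eosinophil attractant eotaxin, rose from 7.66 ± 1.40 to 2134.3 ± 27.2 CPM (278-fold, 8.12 ± 0.35), and Apoe from 66.7 ± 14.8 to 2510.5 ± 141 CPM (37.6-fold, 5.23 ± 0.25). The proteoglycan gene Dcn rose 6.92-fold to 108226 ± 5730.2 CPM and Efemp1, encoding a fibulin of elastic matrix, 27.0-fold. By edgeR 120 genes were higher and 10 lower in young sums at an adjusted p under 0.05 (H2-D1 0.00916, Serping1 0.00924, Ccl11 0.00827, Apoe 0.00916, Dcn 0.00990), and each of them changed over 2-fold.

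Several genes with no reads in newborn sums were present in young ones. Sp100, encoding a nuclear body protein, was at 92.9 ± 1.29 CPM in young sums, 10811 times a floor of 3 reads over both newborn sums. On that floor the steroid sulfate carrier gene Slc10a6 was at 10166 times, the complement gene C4b at 10092 and the phospholipase gene Pla1a at 8326. The floor covers the counting of reads and not the draw of cells, so these ratios are not least fold changes. Pecam1, for example, had 2346 reads in 1 newborn cell. After thinning, Sp100 was read in 9.86 and 22.1% of young cells in experiments 1 and 2 and Slc10a6 in 12.7 and 23.1%. For C4b the shares were 19.7 and 18.3%, and for Pla1a 4.23 and 16.3%. Agmo, Ighm, Lims2 and Bmp5 also had 0 newborn reads and reached 60.4 ± 27.9, 53.9 ± 27.3, 36.4 ± 21.9 and 30.8 ± 0.165 CPM; Ighm encodes the immunoglobulin mu chain of B cells. Serpina3c and Gpm6a, with 4 and 2 reads in the newborn sums, reached 579.9 ± 181 and 276 ± 80.0 CPM. The complement genes Clu and Cfb had 4 and 5 newborn reads and reached 93.9 ± 9.16 and 139 ± 14.5 CPM.

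The 10 genes called lower in young than in newborn sums included Egfl6, Col7a1 and Cdk6. Egfl6, a secreted matrix protein gene, was at 521 ± 93.8 CPM in newborn sums and had 4 reads in young ones, and Col7a1, the collagen of anchoring fibrils, fell from 227 ± 20.6 to 2.85 ± 0.9004 CPM (79.6-fold lower, -6.31 ± 0.41). The G1-phase genes Cdk6 and Ccnd3 were 12.8-fold and 5.66-fold lower, and Myl9 and Cav1, encoding a myosin light chain and caveolin-1, 6.25-fold and 5.94-fold lower. Ccn1, an extracellular signalling protein gene, Mfap2, a microfibril gene, Col6a1 and Tmem119 were 3.84-fold, 3.52-fold, 3.17-fold and 12.3-fold lower (adjusted p from 0.0105 to 0.0468 for these 10 genes). With the experiment as a block, none of the 10 kept its call in edgeR (adjusted p 0.0505 to 0.136). Col3a1 (24856 ± 2456 and 19161 ± 967 CPM) and Sparc (9931 ± 1100.1 and 13607 ± 496 CPM) did not pass. With limma on mean log2(CPM + 1) per cell, where tool, values and genes tested differ at once, Sparc changed sign (-0.45).

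**Figure D2:**
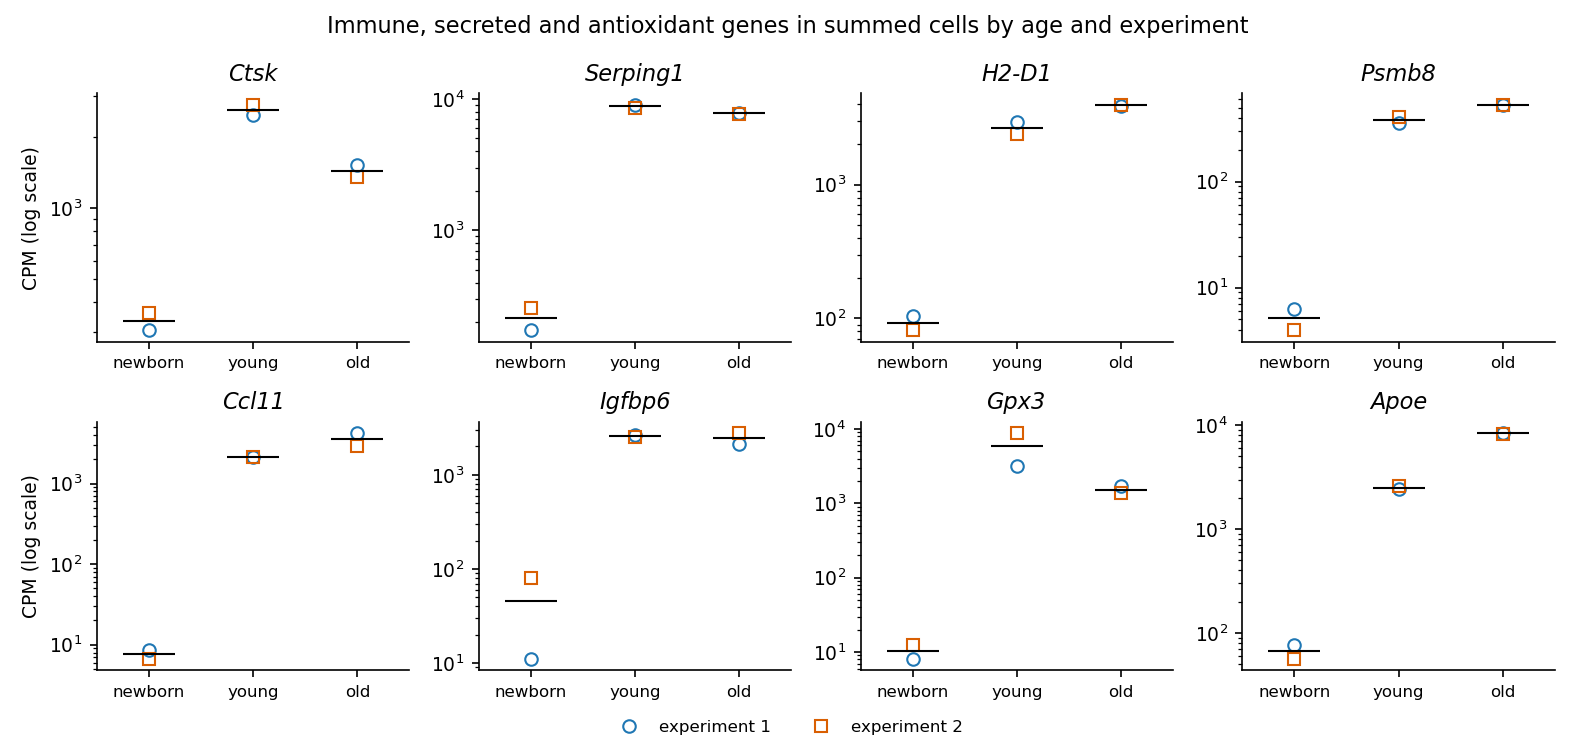
Levels of 8 immune, secreted and antioxidant genes in CPM on a log scale, by age, with 1 point per experiment and a line at the mean of both. Serping1 lies near 215 CPM in newborn and 8768 CPM in young sums, and Ctsk near 332 and 2621 CPM.

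Ctsk, Aldh1a1, Ccl19 and further single genes also rose from newborn to young. Ctsk, the collagen-cleaving protease cathepsin K, rose from 332 ± 40.3 to 2621 ± 185 CPM (7.89-fold, 2.98 ± 0.20, adjusted p 0.0105), and the protease inhibitor genes Timp2 and Serpinf1 5.02-fold and 6.59-fold. Tgfbi, a matrix gene induced by TGF-beta, rose 9.92-fold, Igfbp5, which encodes a binder of insulin-like growth factors, 14.6-fold, and the transcription factor genes Klf4 and Fosb 7.24-fold and 7.04-fold. Aldh1a1, a retinaldehyde dehydrogenase gene, rose 28.4-fold, the glutathione transferase gene Gstm1 21.5-fold and the metallothionein gene Mt1 20.3-fold. Gpx3 rose 586-fold by the mean of young sums that lay apart (3190 and 8757 CPM in experiments 1 and 2). The chemokine gene Ccl19 rose 48.5-fold, the interferon-induced GTPase gene Gbp2 47.7-fold, the tetranectin gene Clec3b 75.0-fold and Cd34 5.66-fold. Tnxb, encoding tenascin-X, and Ccl8 reached 27.6 ± 12.8 and 210.0 ± 22.7 CPM from 34 and 6 newborn reads. Igfbp6 (45.9 ± 49.2 and 2584 ± 112 CPM, adjusted p 0.127) and Ly6a (146 ± 113 and 4459.7 ± 1339.8 CPM, 0.0814) did not pass.

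By list, 8 of 33 rose from newborn to young. Of the 17 lists called in this comparison, higher or lower, fry kept 12. Interferon response and antigen presentation had a median log2 fold change of 2.64 over 37 genes, 31 of them higher in both experiments, and camera gave an adjusted p of 9.8e-23 (adjusted p = 0.0653 with an estimated correlation); 10 members passed over all genes and 24 adjusted over the list alone. The complement list rose by a median of 4.42 (adjusted p 2.2e-09, 6 members over all genes, 7 over the list alone; adjusted p = 0.0655 with an estimated correlation). Antioxidant and metallothionein genes rose by 1.62 (adjusted p 1.1e-10, 8 and 13 members) and matrix proteases and inhibitors by 1.67 (2.7e-10, 4 and 10 members), each at an adjusted p = 0.0655 with an estimated correlation. Chemokines, cytokines and acute phase genes rose by 1.33 (2.3e-08, 3 and 11 members; adjusted p = 0.194 with an estimated correlation). The senescence and secretory list, which includes Igfbp5 and Timp2, rose by 2.28 (1.1e-07, 2 members, and 9 higher and 1 lower over the list alone; adjusted p = 0.0947 with an estimated correlation). Immediate early genes, which respond to stress during cell isolation, rose by 0.77 (0.00113, 2 members, and 7 higher and 1 lower over the list alone; adjusted p = 0.369 with an estimated correlation), a call lost without newborn replicate 1 (adjusted p 0.0682). The 3 measured immune cell markers, Csf1r, Cd74 and Cd68, rose by 5.03 (0.0114, 0 members by edgeR either way; adjusted p = 0.269 with an estimated correlation), and this call was lost whichever of the 6 sums was left out (adjusted p 0.0754 to 0.198).

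Of the 9 lists that fell from newborn to young, proliferation genes had the smallest adjusted p. Their median log2 fold change was -5.46 over 50 genes, 45 lower in both experiments (adjusted p 1.7e-21, 0 members over all genes and 22 over the list alone; adjusted p = 0.0850 with an estimated correlation). The most abundant members, the histone gene H2afz and the tubulin gene Tubb5, were at 1337 ± 133 and 1069 ± 319 CPM in newborn and 645 ± 54.3 and 406 ± 146 CPM in young sums. Imprinted growth genes fell at a median of -2.22, 15 of 19 lower in both experiments (adjusted p 1.4e-04, 0 members either way; adjusted p = 0.274 with an estimated correlation), and among them Peg3 was at 768 ± 106 and 92.9 ± 59.9 CPM. Ribosomal protein genes fell at a median of -0.37, 74 of 81 lower in both experiments (1.4e-04; adjusted p = 0.601 with an estimated correlation). Sterol synthesis genes fell at a median of -0.93 (0.00616; adjusted p = 0.274 with an estimated correlation), a call lost without newborn replicate 1 or young replicate 1 (adjusted p 0.0682 and 0.0659). Papillary markers (-1.32) and the Wnt pathway (-0.40) both fell at an adjusted p of 0.0427 (adjusted p = 0.274 with an estimated correlation). No member of either passed over all genes; adjusted over the list alone, 2 papillary markers were higher and 0 lower, against the direction of the list, and 2 Wnt genes were higher and 3 lower. Both calls were lost with the experiment as a block (adjusted p 0.0919) and without newborn replicate 1, newborn replicate 2 or young replicate 1 (0.0682, 0.101 and 0.0817 for papillary markers, 0.159, 0.194 and 0.0694 for the Wnt pathway, which was also at 0.0640 and 0.0604 without old replicate 1 or 2).

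Markers of other cell types also differed between newborn and young sums. Erythroid genes fell at a median log2 of -8.76, or -5.01 with genes at 0 reads set to their bound (0.00255), dermal papilla genes at -11.90 or -10.0 (0.00616) and keratinocyte genes at -11.82 or -8.07 (0.0260), each at an adjusted p = 0.305 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 3 erythroid, 2 dermal papilla and 0 keratinocyte genes were lower. The keratinocyte genes went both ways: Krt10 was at 19.1 ± 4.66 and 45.5 ± 2.65 CPM and Sfn at 3.95 ± 3.02 and 15.6 ± 8.59 CPM, each higher in young sums in both experiments without passing. Among dermal papilla genes Hhip, encoding a Hedgehog-binding protein, was at 52.2 ± 18.1 CPM in newborn sums with 0 adult reads, and Rspo3, a Wnt agonist gene, at 100.3 ± 18.5 and 0.139 ± 0.175 CPM. The dermal papilla call was lost without newborn replicate 2 or young replicate 1 (adjusted p 0.0853 and 0.0694) and the keratinocyte call without newborn replicate 1, young replicate 1 or young replicate 2 (0.159, 0.0659 and 0.0754). Collagens did not pass (median -0.26, adjusted p 0.0640), nor did the other 15 lists (up to 0.944).

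The number of genes called between newborn and young varied with the fit. With the experiment as a block, 24 genes were higher and 1 lower. Of these, 23 higher genes and 0 lower ones were shared with the fit without a block, so all 10 lower calls were lost. Among the named genes Efemp1, Serping1, Apoe, Ccl11, Clu, Cfb, H2-D1, Psmb10, Tgfbi and Aldh1a1 kept their call there (adjusted p 0.0347 to 0.0460), and the other 37 were at 0.0505 to 0.169. DESeq2 called 1345 genes higher and 1013 lower. On the 6970 genes read in at least 10% of the cells of 1 age, edgeR called 373 higher and 119 lower, and limma on mean log values per cell 453 and 895. Without newborn replicate 1 or 2, 24 and 42 genes were called, all higher, and without either young or either old sum 0. Newborn and adult cells lay in different clusters, so these are differences between populations of fibroblast-like cells that share few clusters. The labels describe a separate staining with Dlk1, CD26 and Sca1 for subsets of newborn fibroblasts and do not say which staining the newborn cells here had, so a difference in selection between newborn and adult cells is not excluded.

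By 18 months, Col3a1, Col5a1 and Sparc had fallen below newborn levels, and Apoe, Ccl11 and H2-D1 had risen above them. Col3a1 fell from 24856 ± 2456 CPM in newborn to 3441 ± 242 CPM in old sums (7.22-fold lower, -2.85 ± 0.16, n = 2 sums per age), Sparc 4.32-fold (-2.11 ± 0.16) and Col5a1, which encodes a chain of type V collagen, 5.44-fold (-2.44 ± 0.23). Col6a1 and Col7a1 fell 4.79-fold and 29.5-fold. Col1a1 (9566 ± 1854 and 2119 ± 819.7 CPM, adjusted p 0.0932) and Col1a2 (10107 ± 1324 and 4764 ± 950.3 CPM, 0.151) did not pass. Apoe rose from 66.7 ± 14.8 to 8332 ± 46.6 CPM (125-fold, 6.96 ± 0.27), Ccl11 464-fold to 3555 ± 930.1 CPM and H2-D1 42.4-fold to 3930.5 ± 35.0 CPM. By edgeR 133 genes were higher and 23 lower (adjusted p 0.00784 for Col3a1, 0.0157 for Sparc, 0.0260 for Col5a1, 0.00537 for Apoe), all by over 2-fold, and with the experiment as a block 46 and 5, of which 43 and 4 were shared.

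Genes without newborn reads and read in old sums included Serpina3g, a serine protease inhibitor gene, at 187 ± 93.9 CPM, 21793 times the floor of 3 reads. Hgf, encoding hepatocyte growth factor, was at 32.9 ± 7.28 CPM, 3829.7 times that floor. Neither ratio is a least fold change. After thinning, Serpina3g was read in 16.7 and 30.7% of old cells in experiments 1 and 2, and Hgf in 5.56 and 4.39%. Gpnmb, encoding a lysosomal glycoprotein, had 2 newborn reads and reached 324 ± 5.17 CPM. In the other direction, Egfl6 at 521 ± 93.8 CPM, Bdnf, a neurotrophin gene, at 46.0 ± 3.301 CPM and the kinase gene Pak3 at 44.3 ± 5.64 CPM in newborn sums had 0 old reads, and Sfrp2, a secreted Wnt regulator gene (431 ± 2.82 CPM), and Hmgb3, a chromatin protein gene (149 ± 74.0 CPM), had 2 each. Cdo1, a cysteine dioxygenase gene, fell from 87.0 ± 42.4 to 0.917 ± 0.530 CPM, Tasp1, a protease gene, from 51.9 ± 5.07 to 3.23 ± 0.866 CPM, Amotl2, which encodes an angiomotin-like protein of cell junctions, from 112 ± 3.92 to 8.57 ± 1.25 CPM and Tnfrsf19, a receptor gene among the papillary markers, from 87.1 ± 2.20 to 7.39 ± 0.998 CPM. Adjusted p for these genes ran from 0.00784 for Gpnmb to 0.0429 for Cdo1.

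The collagen list fell from newborn to old at a median log2 of -2.44, 15 of 19 members lower in both experiments, 6 lower over all genes and 12 over the list alone (adjusted p 5.3e-12; adjusted p = 0.0621 with an estimated correlation). Collagen processing genes fell at a median of -0.85 (2.2e-04, 1 and 4 members; adjusted p = 0.275 with an estimated correlation) and proliferation genes at -5.67, 48 of 50 lower in both experiments (2.1e-20, 0 and 18 members; adjusted p = 0.0869 with an estimated correlation). Imprinted growth genes fell at a median of -10.14, or -6.58 with bounds (2.1e-08, 0 and 9 members), and sterol synthesis genes at -1.53 (6.6e-04), both at an adjusted p = 0.229 with an estimated correlation. The Wnt pathway fell at a median of -0.71 (0.0160, 1 member, and 2 higher and 9 lower over the list alone; adjusted p = 0.229 with an estimated correlation), a call lost with the experiment as a block (0.0511) and without newborn replicate 1, newborn replicate 2 or old replicate 1 (0.0983, 0.123 and 0.116). Ribosomal protein genes fell at a median of -0.36 (0.00744; adjusted p = 0.746 with an estimated correlation), lost without newborn replicate 2 or old replicate 1 (0.218 and 0.847). Erythroid genes (-8.76, or -5.20 with bounds, 0.00374; adjusted p = 0.312 with an estimated correlation) and dermal papilla genes (-8.54, or -6.76 with bounds, 0.00894; adjusted p = 0.275 with an estimated correlation) fell too, the latter not without newborn replicate 2 (0.106).

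Of the lists that rose from newborn to old, interferon response and antigen presentation had the smallest adjusted p (median log2 2.51, adjusted p 5.8e-22, 10 members over all genes and 23 over the list alone). Complement rose too (4.98, 1.2e-10, 6 and 8 members), and both were at an adjusted p = 0.0621 with an estimated correlation. Antioxidant genes (1.52, 1.0e-10, 7 and 13 members) and matrix proteases and inhibitors (1.77, 5.2e-08, 4 and 9 members) rose at an adjusted p = 0.0742 with an estimated correlation. The senescence and secretory list rose by 2.14 (2.0e-06, 3 and 9 members; adjusted p = 0.0869 with an estimated correlation). Chemokines rose by 1.116 (8.1e-05, 3 members, and 11 higher and 1 lower over the list alone; adjusted p = 0.229 with an estimated correlation). Immediate early genes rose by 0.53 (0.00191; adjusted p = 0.378 with an estimated correlation), not without newborn replicate 1 (0.0642), and immune cell markers by 4.68 (0.0216; adjusted p = 0.229 with an estimated correlation), not without any of the 6 sums (0.186 to 0.341). The remaining 16 lists did not pass (0.0715 to 0.908). Of the 17 lists called between old and newborn, higher or lower, fry kept 15.

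Between newborn and old, DESeq2 called 1436 genes higher and 1392 lower. On the 6970 genes read in at least 10% of the cells of 1 age, edgeR called 388 higher and 162 lower, and limma on mean log values per cell 396 and 1426. Without newborn replicate 1 or 2 edgeR called 32 and 47 genes, without young replicate 1 or 2 it called 10 and 28, and without either old sum 0. With the experiment as a block, Sp100, Gpnmb, Col3a1, Sparc, Efemp1, Dcn, Mfap2, Apoe, Ccl11, Cfb, H2-D1, Psmb8, Ccn1, Tgfbi, Aldh1a1, Gstm1 and Cd34 kept their call (adjusted p 0.0250 to 0.0497), and the other 21 named genes were at 0.0511 to 0.163.

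**Figure D3:**
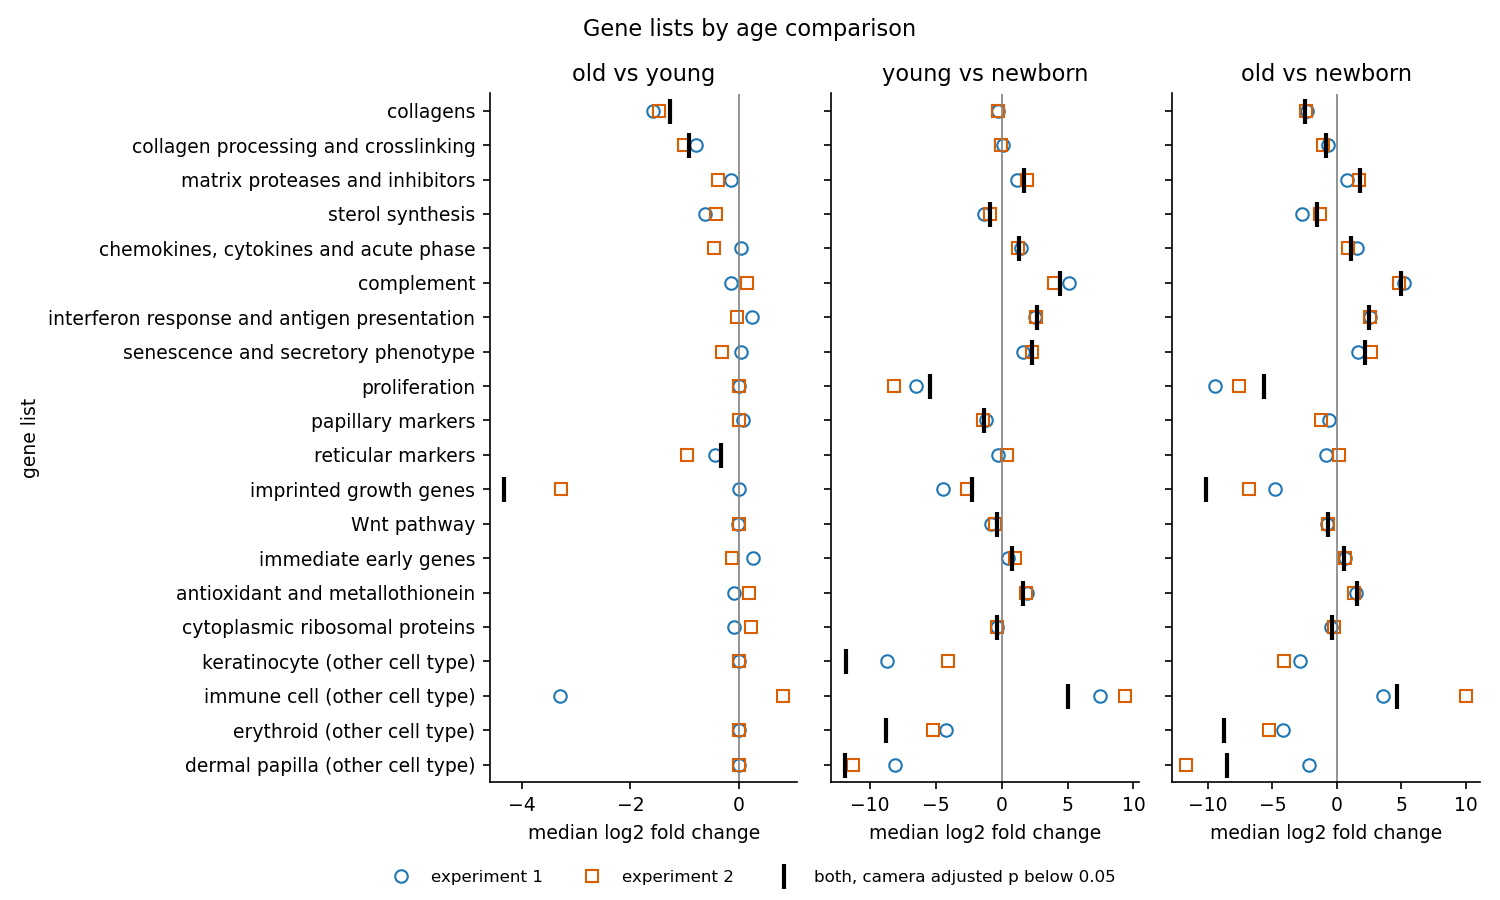
Median log2 fold change of 20 gene lists in each age comparison, with 1 point per experiment and a black bar for both experiments where camera gave an adjusted p below 0.05. The collagen list lies at -1.58 and -1.48 between old and young.

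Cells with reads of several proliferation genes made up a higher share of newborn than of young or old cells in both experiments. A read in at least 5 proliferation genes was found in 35.4% (95% exact interval 28.0 to 43.4) and 37.4% (27.4 to 48.1) of newborn cells in experiments 1 and 2, in 2.82% (0.773 to 7.06) and 10.6% (5.40 to 18.1) of young cells and in 3.97% (1.30 to 9.02) and 3.51% (0.964 to 8.74) of old cells. Without thinning the shares were 36.7 and 39.6%, 4.93 and 14.4%, and 3.97 and 7.02%. The intervals cover counting error only. H2afz and Tubb5, members of the list, were read in 73.0 to 91.2% and 76.2 to 95.6% of the cells of every sum after thinning (73.8 to 92.3% and 76.98 to 97.8% without), so the share is not a count of dividing cells. A cluster led by Pclaf, Stmn1 and Birc5 held 18 of 158 and 7 of 91 newborn cells. The exact permutation p was 0.333 for young and for old against newborn, the smallest that 2 against 2 values allow (two-sided), and 1 for old against young. The differences depended on the number of genes asked for. Young minus newborn was -29.7 percentage points with at least 5 genes, -22.0 with at least 3 and -14.7 with at least 10, and old minus young was -2.96, -11.3 and 0.

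Distance between cells differed between old and young in experiment 1 (0.0212 higher in old) and hardly in experiment 2 (-2.3e-04). The mean of 1 minus the Spearman correlation over pairs of cells was 0.670 and 0.678 in newborn, 0.675 and 0.667 in young and 0.696 and 0.666 in old cells (exact permutation p 1 for old against young, 0.667 for young against newborn and 1 for old against newborn; 2 against 2 values cannot go below 0.333). The old value exceeded the young one on 7 of 9 plates (differences from -0.0142 to 0.0380). The squared coefficient of variation of genes with matched means was higher in old than in young cells by a median log2 of 0.18 and 0.41, with 65.8 and 78.5% of genes higher. In cells matched on genes detected the difference was 0.00782 and 0.0366. Without matching, variability was higher in old than in newborn cells by 0.25 and 0.45; between young and newborn it was 0.06 and 0.02. Scores of papillary and reticular markers correlated across cells at r of -0.0839 and -0.398 in newborn, -0.124 and -0.126 in young and 0.0570 and -0.0786 in old cells. The SD of the score difference was 0.444 and 0.670, 0.295 and 0.321, and 0.270 and 0.260. The median number of genes with a read at 100000 reads was 1799 and 2226 in newborn cells, 1648 and 2043 in young and 1503.5 and 1700.5 in old cells, and 2192.5 and 2746, 1968 and 2515.5, and 1813.5 and 2137 without thinning (exact permutation p 0.667 for old against young, 0.333 for old against newborn). These permutations ignore the shared experiment. Within experiments 1 and 2 the old median differed from the young one by -144.5 and -342.5 genes.

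**Figure D4:**
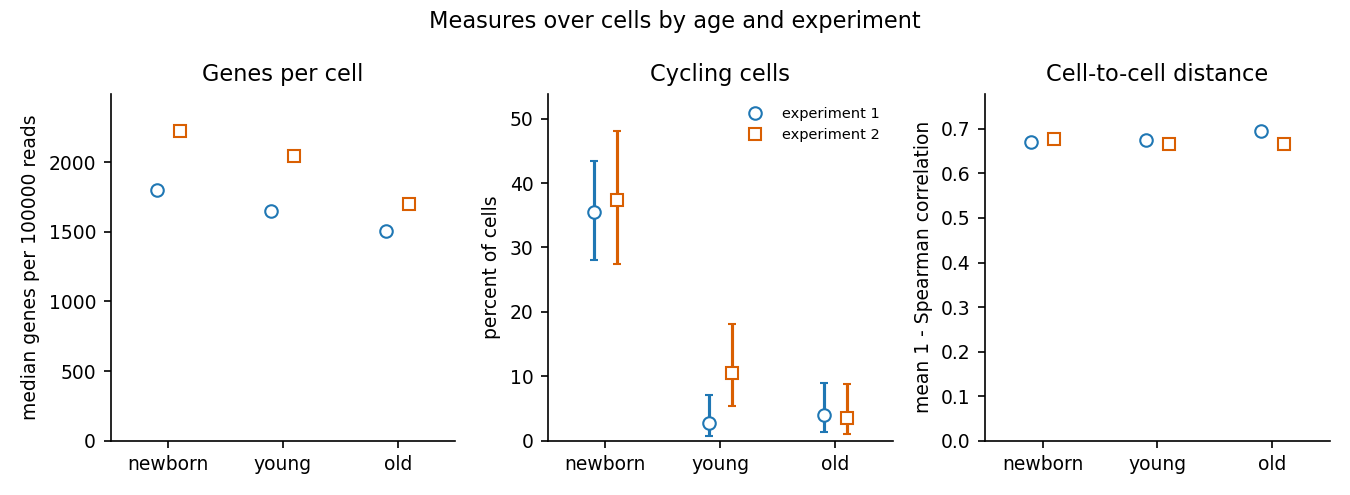
Median genes per 100000 reads, percent of cells with a read in at least 5 proliferation genes (titled cycling cells) with 95% exact intervals, and mean cell-to-cell distance (1 minus Spearman correlation), by age, with 1 point per experiment. That share is 35.4 and 37.4% in newborn cells.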

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

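None of the tests in this part was chosen after its result was seen.

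Many old wells that were left out held mostly mitochondrial reads. Among the 78 old wells left out the median mitochondrial share was 73.2% of gene reads, with a median of 97.5 genes; the 41 young wells left out had 57.1% and 129 genes, and the 7 newborn wells 4.93% and 653 genes. By experiment 20.8 and 28.3% of old wells were left out, against 10.7 and 18.8% of young and 1.25 and 5.21% of newborn wells. These wells drew attention because no comparison uses them. Spike-in entries drew attention for the same reason. The 92 entries held 80 reads in all, in 2 cells, and 78 of these lay in 1 cell.

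Kept old cells had fewer genes with a read than young cells, with a difference in medians of -144.5 in experiment 1 and -342.5 in experiment 2 at 100000 reads per cell. Reads taken by abundant genes are argued against, since 94.7% of the difference in 1 experiment and 110% in the other stayed without the 100 most abundant genes. Damaged cells may account for part of it. Among cells at or below the young median mitochondrial share (40 old and 71 young cells in experiment 1, 21 and 52 in experiment 2), 48.8% of the difference stayed in experiment 2, below the bound of 50%, and 128% in experiment 1. By the bound set, single plates stay open. The old median lay below the young one on 7 of 9 plates, 1 short of that bound. Those 7 included all 4 plates of experiment 2 and differed by -478 to -80 genes, the others by 6 and 38. This argues against 1 plate setting the difference in experiment 2. A lower RNA content of old cells is an untested biological explanation.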

How the results depend on the processing

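Chosen after seeing the data were the tests on genes read in at least 10% of cells, limma and camera on mean log values per cell, the first runs only, and the fits without 1 young cell. Over all results and alternatives, 2515 values kept their direction and their side of the threshold, or moved within the spread between experiments; 739 were weaker, 82 stronger, 25 reversed and 6 moved beyond that spread. Except where the setting itself tests fewer genes or sums, the cause was not tested.

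The number of genes called changed with the tool and with the genes tested. DESeq2 called 1047 genes between old and young, 2358 between young and newborn and 2828 between old and newborn, where edgeR called 0, 130 and 156. With genes read in at least 10% of cells the counts were 9, 492 and 550, and with limma on mean log values per cell, over those same 6970 genes in place of 16684, 8, 1348 and 1822, so tool, values and genes differed at once. Its median over all genes lay at a log2 of -0.09, -0.26 and -0.38, and its counts of lower genes include that shift. Without a filter on low counts 2 genes passed between old and young. With each cell thinned to the same reads, 254 genes were called between young and newborn and 281 between old and newborn.

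With the experiment as a block, 25 genes were called between young and newborn (24 higher, 1 lower) and 51 between old and newborn (46 higher, 5 lower). With only the 2 ages in the fit these counts were 0 and 44, from fewer sums to estimate the spread.

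No list passed in any comparison with an estimated correlation in camera (0 lists in each of the 3). That setting also lowers the degrees of freedom to the 3 residual ones of the fit, so few lists could pass. A call lost there does not by itself mean that the genes of a list were correlated. Between old and young the adjusted p was then 0.102 for collagens, 0.597 for collagen processing and crosslinking, and 0.767 for both reticular markers and imprinted growth genes. With fry 1 list passed between old and young, the collagens, while collagen processing was at 0.0857 and reticular markers and imprinted growth genes both at 0.518. Of the 17 lists called between young and newborn fry kept 12 and lost 5. Of the 17 called between old and newborn it kept 15 and lost 2. On mean log values per cell (the 6970 genes) 9 lists passed (3 higher, 6 lower), and the imprinted growth genes were at 0.330.

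A few genes without a call changed sign. Between old and young Ly6a was at a log2 of -0.0120 with thinned cells and -0.10 with limma on mean log values, Pdgfra at -0.14 with the stricter cell filter and -0.59 with limma, and Xist at -0.0760 and -0.0146 in the same order. Sparc, between young and newborn, was at -0.45 with limma.

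Among the cell measures, the stricter cell filter gave a distance difference of -0.00860 between old and newborn, variability ratios (log2) of -0.0711 between young and newborn and 0.12 between old and newborn, and a share of cells with a read in at least 5 proliferation genes 34.6 percentage points lower in young than in newborn (-34.6). Euclidean distance over the 500 most variable genes gave ratios of 1.03 (young over newborn) and 1.06 (old over newborn). Asking for at least 3 proliferation genes, the difference in that share was -11.3 points between old and young and -22.0 between young and newborn, and with at least 10 genes -14.7 between young and newborn.

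Leaving out 1 of the 6 sums at a time left an age with a lone sum, assumed to vary like the others. Genes called then ran from 0 to 42 between young and newborn and from 0 to 47 between old and newborn, and lists called from 2 to 7 between old and young and from 11 to 16 between young and newborn. The adjusted p ran from 1.9e-09 to 0.136 for imprinted growth genes and from 0.0175 to 0.447 for reticular markers. Log2 fold changes between old and young ran from -0.42 to 0.14 for Cd34, -0.0163 to 0.10 for Dcn, -0.51 to 0.0370 for Fos, -0.0013 to 0.52 for Igfbp5, -0.26 to 0.37 for Ly6a, -0.21 to 0.56 for Pdgfra and -0.13 to 1.00 for Xist.

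In experiment 1 or 2 alone, distance differences ran from -0.0116 to 0.0263 between old and newborn, -2.3e-04 to 0.0212 between old and young and -0.0114 to 0.00508 between young and newborn. The correlation of papillary and reticular scores differed by -0.0398 to 0.272 between young and newborn, and the share of cells with a read in at least 5 proliferation genes by -7.07 to 1.15 points between old and young.

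Depth limits what can be said of genes with few reads. A gene with 0 reads in both sums of an age was set against a floor of 3 reads, which leaves out the draw of cells. A gene with 0 reads in all 735 cells was bounded at 0.408% of cells with a read (counting error only). This does not limit the share of cells that express it. With 2 sums per age, edgeR on simulated sums recovered 1.49% of genes changed 4-fold and 37.9% of those changed 16-fold between old and young.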

Other observations

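Chosen after its result was seen was the fit without 1 young cell; the other tests in this part were set down before their results were seen.

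One young cell of experiment 2 carried newborn genes. With 748650 reads on 2980 genes, it had H19 at 8097 CPM and Igf2 at 1429 CPM, an imprinted growth-regulating RNA and an imprinted growth factor gene, Dlk1, which encodes a Notch-like surface protein, at 516 CPM, Peg3 at 3505 CPM and Col1a1 at 7245 CPM. It had 0 reads of Ly6a, Cyp2f2 and H2-D1, which were read in 98.4, 79.7 and 96.7% of young cells and in 18.5, 11.6 and 22.9% of newborn cells. H19, Igf2 and Dlk1 were read in 44.2, 30.5 and 34.9% of newborn cells, and in 5, 5 and 1 of the 246 young cells. The cell held 6.18% of the young reads of imprinted growth genes. A test of whether it alone set the result of the imprinted growth genes list, old vs young, was written after the cell was seen. Without the cell the adjusted p was 0.000737, against 7.3e-05 with it, so this cell alone did not make the call. The call was lost without young replicate 2, the experiment of this cell (adjusted p 0.136), and at an adjusted p = 0.767 with an estimated correlation. Whether the cell was a misplaced newborn cell was not tested.

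Ighm, encoding the immunoglobulin mu chain, was read in adult cells without the immune gene Ptprc. After thinning, 9.15 and 8.65% of young cells and 11.9 and 14.0% of old cells had an Ighm read (9.15 and 10.6%, and 11.9 and 14.0% without thinning), against 0 newborn cells, while Ptprc had 0 reads in all 735 cells.

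The lower collagen list in old sums may reflect age. The ratios here compare mean CPM of thinned cells with 1 added, and so differ from the fold changes of the sums (-1.58 and -1.48). Old and young cells were matched on genes detected (106 cells of each age in experiment 1 and 70 in experiment 2). This left its median log2 ratio at -1.15 and -1.09, from -1.21 and -1.52 before matching, which argues against fewer genes detected. Thinned cells weigh equally in the ratios before matching, which argues against a few deep cells. The test set for deep cells, the median difference in mean log2(CPM + 1) per cell, gave -0.88 and -1.24. It also used thinned cells and changed only the log scale, so it bears on a few cells with high levels. The ratio was below 0 on 9 of 9 plates (-2.10 to -0.77), which argues against single plates. Age stays open as an untested biological explanation, and differences between mice, in the response to digestion or in sorting were not separated from it.

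The higher gene-wise variability of old cells may come from their fewer detected genes. In cells matched on genes detected, the median log2 ratio was 0.00782 and 0.0366, from 0.18 and 0.41. Leaving out the 10% of cells farthest from the others left it at 0.18 and 0.40, which argues against a few outlying cells. A change in variability with age is not excluded by the matching, which also removes cells, and was not tested apart from it.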
